A study of Homo sapiens with 6 samples.

How the data were processed

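Total RNA of 6 samples of MIA PaCa-2, an established human pancreatic cancer cell line, was sequenced: 3 libraries from cells with a knockout of the long non-coding RNA gene LINC00901 (KO 1 to 3) and 3 from vector control cells (vector control 1 to 3). Each library was placed in its group by its title and genotype label. The labels do not state whether the libraries came from separate cultures, clones or days, so the p-values measure the spread between these samples, which may be technical.

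The authors deposited a single table of FPKM (fragments per transcript length and library size) with 1 column per library and values given to 2 decimals. Per the submitters' processing notes, cutadapt, FastQC and HISAT2 were used with the human build hg19. Their versions, the tool that computed FPKM, the gene annotation and the use of strand are not given in the sources used here. FPKM is scaled by the authors to library size and gene length, so depth cannot be read from it directly. A search for whole-read steps was made among low values of short genes with a single annotated transcript. It found none, and the best step in any library reached a concentration of 0.425 on a scale where exact multiples give 1. Depth is therefore unknown, and the number of libraries and the spread between them set the precision. Without stated strand use, reads of a gene and of an antisense partner cannot be told apart. The table held 18268 rows, of which 3855 were at 0 in all libraries and 990 joined the symbols of overlapping or neighbouring genes. A joined row was kept as 1 unit and is named with all its symbols. The 13 rows of mitochondrially encoded genes were at 0 in every library although every cell uses these genes, so an exact 0 here can be an unmeasured value, and a gene is said only to be listed at 0.

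The main test was limma (lmFit, then eBayes with a mean-variance trend) on log2(FPKM + 1), KO against vector control, without covariates. Genes with at least 1 FPKM in at least 3 of the 6 libraries were tested, 9624 in all. The test was two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. Log2 fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. Group values are given as mean ± SD of FPKM with n = 3 libraries per group, and SE is the standard error of the log2 fold change from limma.

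Before the data were examined, 24 gene lists were fixed from textbook knowledge: MYC targets, the m6A RNA methylation machinery, G1/S and DNA replication, mitosis, p53 targets. They also held epithelial junction and keratin genes, mesenchymal genes, type I interferon response, NF-kB and inflammatory cytokine genes, and hypoxia and glycolysis. Further lists were the unfolded protein response, cholesterol biosynthesis, MAPK feedback and immediate early genes, ribosomal proteins, nuclear and mitochondrial genes of the respiratory chain (as separate lists). The last were replication-dependent histones, neuroendocrine genes, pancreatic acinar and ductal genes, leukocyte genes, the genomic neighbours of LINC00901, HOX genes, YAP/TAZ targets, and autophagy and lysosome genes. Of the 878 list entries, 773 had a row under their own symbol, 13 under another symbol taken from the RefSeq annotation of GRCh38, 77 only within a joined row and 15 no row. Members with a row of their own entered the test. Lists with at least 5 tested members, 19 of them, were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Beside it, camera with an estimated correlation, camera on ranks and fry were run. Counts of called members are given over all genes tested and adjusted over the list alone.

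The rule for the genes the text names was also fixed before the data were examined. It took LINC00901, MYC and IGF2BP2 whatever their result. It then took the 10 highest and 10 lowest log2 fold changes among called genes whose groups did not overlap and whose higher group mean was at least 5 FPKM. For each list past the camera test or with at least 3 called members it added up to 2 called members with the highest and 2 with the lowest fold change. Among the genes named outside this rule, KLK8;KLK9, BIRC3, CXCL5, IER3, NFKBIA, NFKB1, ETV4, HIST1H3F, IFIT3, OASL, HOXB9, CTSL, MAP2, LYZ, HLA-DRA, TMEM39A and TIMMDC1 are list members or neighbours chosen after their values were seen.

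The alternatives fixed before the data were examined were other pseudocounts, no filter or a stricter one, median scaling, quantile normalization, limma without the trend, robust limma with array weights, the replicate number as a block, each library left out in turn, and other thresholds. Alternatives chosen after seeing the data were a term for a division of the libraries that crosses the groups, that term together with an estimated correlation, a correction for GC content and transcript length, and list tests that included joined rows. GC content, length and gene order came from GENCODE 29 on GRCh38. Because that build differs from the authors', no coordinates are given.

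The tests were tried on simulated data for the 9624 genes with the real means and spreads and 200 genes changed, in 20 runs. The gene test recovered 1.5% of genes changed by 0.5 on the log2 scale, 46.7% of those changed by 1, 84.4% of those changed by 2 and 98.5% of those changed by 4, and 4.76% of its calls were false. The simulated genes were independent of each other, so these shares leave out correlation between genes. Camera was also run on the unchanged simulated data, where 3.95% of its tests of the 19 lists had p below 0.05. This does not check the real camera calls, because members of several lists moved together in the real data. Estimated correlations were 0.788 for G1/S, 0.528 for ribosomal proteins and 0.509 for MYC targets, far above the preset 0.01. They were small for NF-kB (-0.027), cholesterol (0.033), MAPK (0.034) and YAP/TAZ (0.054). The unadjusted camera p of the NF-kB list still rose from 1.72e-17 to 7.44e-04 with its estimate. A call lost with an estimated correlation therefore does not rest on correlation between genes alone. Computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15, and figures were drawn with matplotlib 3.10.9.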

Results

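The transcriptomes of MIA PaCa-2 cells with a knockout of LINC00901 were compared with those of vector control cells, in 3 libraries per group. The values were FPKM, which summed to between 123107 (KO 1) and 134389 (vector control 3) per library, with 9153 to 9612 rows at 1 FPKM or above. LINC00901 itself was not analysed here because 0 of the 18268 rows named it. The knockout was therefore not checked in these values, and every direction rests on the labels. Of the 23 listed genes near LINC00901 on chromosome arm 3q, 8 had no row, 4 were tested and 0 were called. The log2 fold changes of the 4 tested genes ran from -0.12 for TMEM39A to 0.46 for TIMMDC1. The rest lay below the filter, among them GAP43 (at most 0.07 FPKM) and LSAMP (listed at 0 in all 6 libraries). A change in those genes could not be seen here.

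The libraries did not fall into the groups by overall similarity alone. Across the 9624 tested genes, vector control 2 and 3 correlated at r = 0.979 and KO 2 and 3 at r = 0.970. Vector control 1, in contrast, correlated at r = 0.932 with KO 3 and at r = 0.904 with vector control 2. KO 1 lay between the others, at r = 0.935 with KO 3 and r = 0.921 with vector control 3. These correlations are across genes, which are not independent replicates. Replication-dependent histone genes divided the libraries in another way, with KO 1 beside vector control 2 and 3. They made up 6.28% of the FPKM sum in vector control 1, 5.21% in KO 2 and 5.25% in KO 3. Their share was 2.83% in vector control 2, 3.29% in vector control 3 and 3.03% in KO 1.

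**Figure D1:**
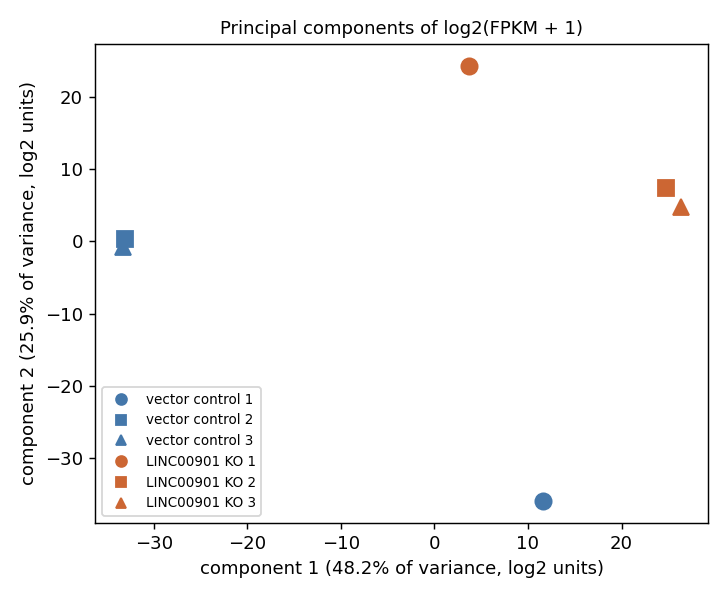
Principal components of log2(FPKM + 1) over the 9624 tested genes, component 1 (48.2% of variance) on the horizontal axis and component 2 (25.9%) on the vertical axis, both in log2 units, with 1 point per library (blue, vector control; orange, LINC00901 KO; the symbol gives the replicate). Vector control 2 and 3 lie together, KO 2 and 3 lie together, and vector control 1 and KO 1 each lie apart from the rest of their group.

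Knockout cells had lost most of the transcript of several secreted proteins. The joined row of the matrix metalloproteinase genes MMP3 and MMP10, whose products degrade extracellular matrix, stood at 237.42, 207.65 and 210.15 FPKM in the vector controls and at 0.05, 0 and 0 in the KO libraries (log2 fold change -7.75, SE 0.14, adjusted p = 8.0e-07). MMP1, the interstitial collagenase, fell from 306.61, 194.85 and 203.79 FPKM to 0, 5.02 and 5.18 (log2 fold change -6.11, SE 0.68, adjusted p = 0.0102). The secreted hormone gene STC1 fell from 27.8 ± 5.13 to 0.333 ± 0.126 FPKM, the WNT antagonist DKK1 from 21.3 ± 11.1 to 0.827 ± 0.909, and the neutrophil chemokine CXCL8 from 43.9 ± 20.9 to 4.39 ± 0.450 (SD, n = 3 per group). Their log2 fold changes were -4.42, -3.61 and -2.97, with adjusted p of 1.37e-04, 0.0135 and 0.00799.

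The other genes with the lowest fold changes were RGS4, a regulator of G protein signalling, which fell from 26.1 ± 2.83 to 0.187 ± 0.0513 FPKM (log2 fold change -4.51, adjusted p = 3.95e-05), and SCG2, the granin secretogranin II. SCG2 stood at 18.97, 17.54 and 20.24 FPKM in the vector controls and at 0.49, 0 and 0.14 in the KO libraries (-4.06, adjusted p = 1.98e-04). The actin-associated PDLIM1, the aldose reductase gene AKR1B1 and the betaine transporter gene SLC6A12 fell by 2.82, 2.79 and 2.76 on the log2 scale, with adjusted p of 4.61e-04, 0.00337 and 3.3e-04. AKR1B1 was the most abundant of the 3 in the vector controls, at 66.9 ± 16.8 FPKM against 8.67 ± 1.62 in the KO libraries (n = 3 per group).

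Among the genes that rose were 3 kallikrein-related serine protease genes that lie next to each other among the tested genes in GENCODE 29. KLK5 rose from 13.8 ± 2.98 to 71.9 ± 17.8 FPKM, KLK6 from 79.0 ± 23.2 to 264 ± 21.8 and KLK7 from 1.91, 3.82 and 3.40 to 14.11, 13.87 and 12.55 (SD, n = 3 per group). Their log2 fold changes were 2.29, 1.77 and 1.87, with adjusted p of 0.00842, 0.0214 and 0.0122. The joined row KLK8;KLK9, named after its value was seen, was also called, at 1.43. The GATA-type transcriptional repressor gene TRPS1 had the highest fold change, from 1.77 ± 0.929 to 12.1 ± 1.04 FPKM (log2 fold change 2.30, SE 0.25, adjusted p = 0.00904). ALDH1A1, a retinaldehyde dehydrogenase gene, rose from 153 ± 26.4 to 457 ± 17.9 FPKM (1.59, adjusted p = 0.00904). MOB1A, which encodes an activator of the LATS kinases of the Hippo pathway, rose by 1.75 on the log2 scale and the core fucosyltransferase gene FUT8 by 1.63. FAM129A rose by 1.66, HIST1H2AC by 1.56 and KAZALD1 by 1.46. Adjusted p of these 5 ran from 0.0111 for HIST1H2AC to 0.0351 for FAM129A. Histone genes have near-identical copies, so the value of HIST1H2AC depends on how reads shared between copies were assigned.

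**Figure D2:**
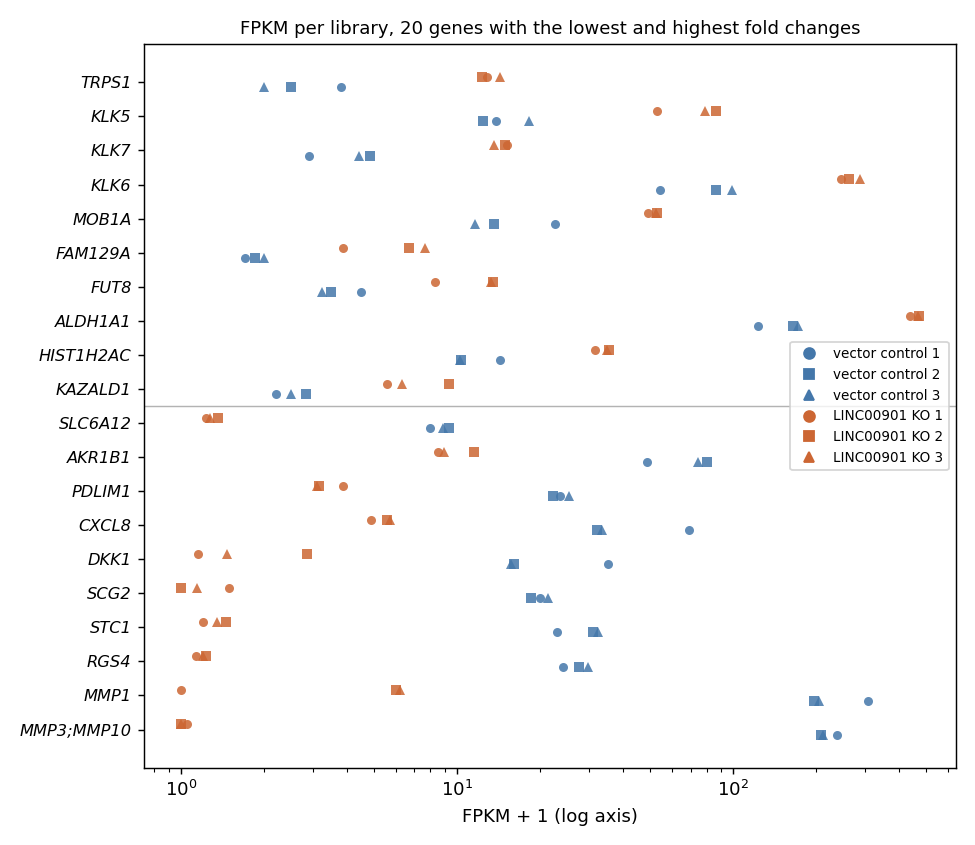
FPKM + 1 of each library on a log axis for the 10 genes with the highest and the 10 with the lowest fold changes that the naming rule took (blue, vector control; orange, LINC00901 KO; each point is 1 library and the symbol gives the replicate). In each of the 20 genes, the 3 KO libraries lie on one side of the 3 vector controls.

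Over all tested genes, limma called 130. Of these, 49 were higher in the KO libraries, 26 of them with a log2 fold change of 1 or more. The other 81 were lower, 73 of them with -1 or less. With quantile normalization the same number divided into 31 higher and 99 lower. The balance turned with robust limma and array weights (2596 higher, 1424 lower) and without vector control 1 (841 higher, 488 lower). In 2288 tested genes, or 23.8%, the 3 KO libraries did not overlap the 3 vector controls, where interchangeable libraries would give 10% on average. Genes moved together, so this excess alone does not show an effect of the knockout. At an unadjusted limma p below 0.05 the groups had 1685 genes. Vector control 1, KO 2 and KO 3 against the rest had 2485.

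The count of calls depended on single libraries and on the fit. It was 25 without KO 3, 29 without KO 2, 39 without vector control 2, 39 without vector control 3, 121 without KO 1 and 1329 without vector control 1. It was 4020 with robust limma and array weights, 59 with a filter at 5 FPKM, 241 without a filter and 31 at an adjusted p below 0.01.

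Genes of the NF-kB pathway and its inflammatory cytokine targets were lower as a group in the KO libraries. Of 20 tested members, 6 fell, 0 rose and 14 did not pass over all genes. Adjusted over the list alone, 15 were lower and 0 higher. CXCL8 and TNFAIP3, which encodes the ubiquitin-editing inhibitor A20, had the lowest fold changes. TNFAIP3 went from 7.08 ± 2.32 to 0.727 ± 0.428 FPKM (n = 3 per group; log2 fold change -2.21, SE 0.28, adjusted p = 0.0179). The other 4 that fell, named after their values were seen, were the inhibitor of apoptosis gene BIRC3 (-1.72), the chemokine gene CXCL5 (-1.71), the early response gene IER3 (-1.51) and NFKBIA (-1.46), which encodes the NF-kB inhibitor IκBα. The subunit gene NFKB1 stood at 5.56 ± 2.77 FPKM in the vector controls and 5.26 ± 0.670 in the KO libraries. Chemokine targets and feedback inhibitors of the pathway were both among the genes that fell. The median log2 fold change of the list was -0.94 (camera adjusted p = 3.27e-16). The list also passed with an estimated correlation (adjusted p = 0.0141) and with fry (adjusted p = 1.83e-04). It lost the call when a term for the division of the libraries and an estimated correlation were used together (adjusted p = 0.0576). The list mean of the KO libraries lay between -1.15 and -1.07 relative to the control mean. The vector controls themselves ran from -0.02 to 0.04, so the mean of this list did not divide the libraries within either group. Single members did, in opposite directions. CXCL8 stood at 67.99 FPKM in vector control 1 against 31.16 and 32.59 in vector control 2 and 3, and TNFAIP3 at 4.41 against 8.16 and 8.66. With the division fitted beside the groups, 2 of the 20 members were called for it.

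The other 7 lists past camera were also lower in the KO libraries, with smaller shifts. Camera compares a list with the other genes, and the median log2 fold change of all tested genes was 0.08. Part of a small shift may therefore be relative to this raised background. After median scaling, which brought that median to 0.01, 8 lists passed. Each of the other 7 lists lost the call with an estimated correlation and with fry. Of 31 tested MAPK feedback and immediate early genes, 3 fell and 0 rose over all genes. Adjusted over the list alone, 6 were lower and 1 higher. The AP-1 subunit gene JUN fell from 29.7 ± 1.70 to 14.0 ± 2.17 FPKM (n = 3 per group; log2 fold change -1.04, adjusted p = 0.0303) and the transcription factor gene KLF4 from 2.53 ± 0.798 to 0.533 ± 0.201 (-1.19, adjusted p = 0.0484). The third, ETV4, fell by 1.03. The median of the list was -0.34 (camera adjusted p = 9.85e-04; adjusted p = 0.261 with an estimated correlation), and the call was lost with a filter at 5 FPKM (0.263). Of 22 tested mesenchymal genes, only SNAI2, which encodes the transcription factor SLUG, fell over all genes, from 8.65 ± 0.218 to 0.940 ± 0.479 FPKM (n = 3 per group; log2 fold change -2.35, adjusted p = 0.00481). Adjusted over the list alone, 6 were lower and 2 higher. The median was -0.23 (camera adjusted p = 0.00413; adjusted p = 0.370 with an estimated correlation). The call was lost with a filter at 5 FPKM (0.141) and after GC and length correction (0.0564). Of 18 tested YAP/TAZ targets, 2 fell and 0 rose over all genes, and 4 were lower adjusted over the list alone. The kinase gene NUAK2 fell by 1.96 (adjusted p = 0.00307) and GADD45A, which is also in the p53 list, by 1.40 (adjusted p = 0.0466). The median was -0.20 (camera adjusted p = 0.0260; adjusted p = 0.370 with an estimated correlation), and the call was lost without vector control 1 (0.118) and without KO 3 (0.0583). It was also lost with a filter at 5 FPKM (0.141), quantile normalization (0.0611), robust limma and array weights (0.0831), camera on ranks (0.149) and GC and length correction (0.0706). For KO 1 against vector control 2 and 3 alone the median was 0.04. Of 27 tested hypoxia and glycolysis genes, NDRG1 alone fell over all genes, from 5.47 ± 2.52 to 0.727 ± 0.00577 FPKM (n = 3 per group; log2 fold change -1.81, adjusted p = 0.0466). Adjusted over the list alone, 2 were lower. The median was -0.13 (camera adjusted p = 0.0152; adjusted p = 0.370 with an estimated correlation), and the call was lost without vector control 2 (0.0624), without KO 3 (0.0589) and with the division as a term (0.0870). It was also lost with a filter at 5 FPKM (0.141) and quantile normalization (0.133).

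In 3 lists past camera no single gene was called over all genes. Cholesterol biosynthesis genes had a median of -0.31 over 26 tested members, 21 of them below 0 and 1 lower adjusted over the list alone (camera adjusted p = 6.47e-04; adjusted p = 0.261 with an estimated correlation). Ribosomal protein genes had a median of -0.13 over 68 members, 51 of them below 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 6.47e-04; adjusted p = 0.612 with an estimated correlation). The call was lost after quantile normalization (0.990), without vector control 3 (0.0837) and with the division as a term (0.0692). For KO 2 and 3 against vector control 1 alone the median was 0.06. MYC target genes had a median of -0.14 over 44 members, 31 of them below 0 and 0 past the threshold adjusted over the list alone (camera adjusted p = 0.00240; adjusted p = 0.612 with an estimated correlation). The MYC target list also moved with the division of the libraries, with a mean of 0.34 in vector control 1 and -0.37 in KO 1 against the control mean. Its adjusted p was 0.339 without vector control 1, 0.171 without KO 1, 0.0611 after quantile normalization and 0.807 with robust limma and array weights. With the division as a term the MYC target list stayed lower (camera adjusted p = 1.49e-07). The call was lost with that term and an estimated correlation together (0.232). The median of the list was -0.24 for KO 1 against vector control 2 and 3, and -0.35 for KO 2 and 3 against vector control 1. In 4 further lists past camera vector control 1 lay below KO 1. Their means in vector control 1 and KO 1 were -0.25 and -0.02 for ribosomal proteins, -0.25 and 0.01 for hypoxia, -0.33 and -0.20 for cholesterol and -0.26 and -0.22 for mesenchymal genes. For ribosomal proteins vector control 1 lay below all 3 KO libraries, the lowest of which was at -0.19.

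MYC stood at 18.20, 39.54 and 17.44 FPKM in the vector controls and at 12.98, 14.23 and 6.34 in the KO libraries (log2 fold change -1.07, SE 0.39). With adjusted p = 0.234 it did not pass, although the groups did not overlap, and it was called only with robust limma and array weights (adjusted p = 0.0296). IGF2BP2, which encodes an m6A-reading protein that stabilizes mRNA, stood at 9.46 ± 1.79 and 5.44 ± 1.98 FPKM (n = 3 per group; log2 fold change -0.73, SE 0.25, adjusted p = 0.215) and did not pass either. Of the 22 tested members of the m6A machinery list, 0 were called over all genes and 0 adjusted over the list alone. The list had a median of 0.04 and a mean of 0.08, while camera, which compares it with the other genes, placed it lower (adjusted p = 0.715).

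**Figure D3:**
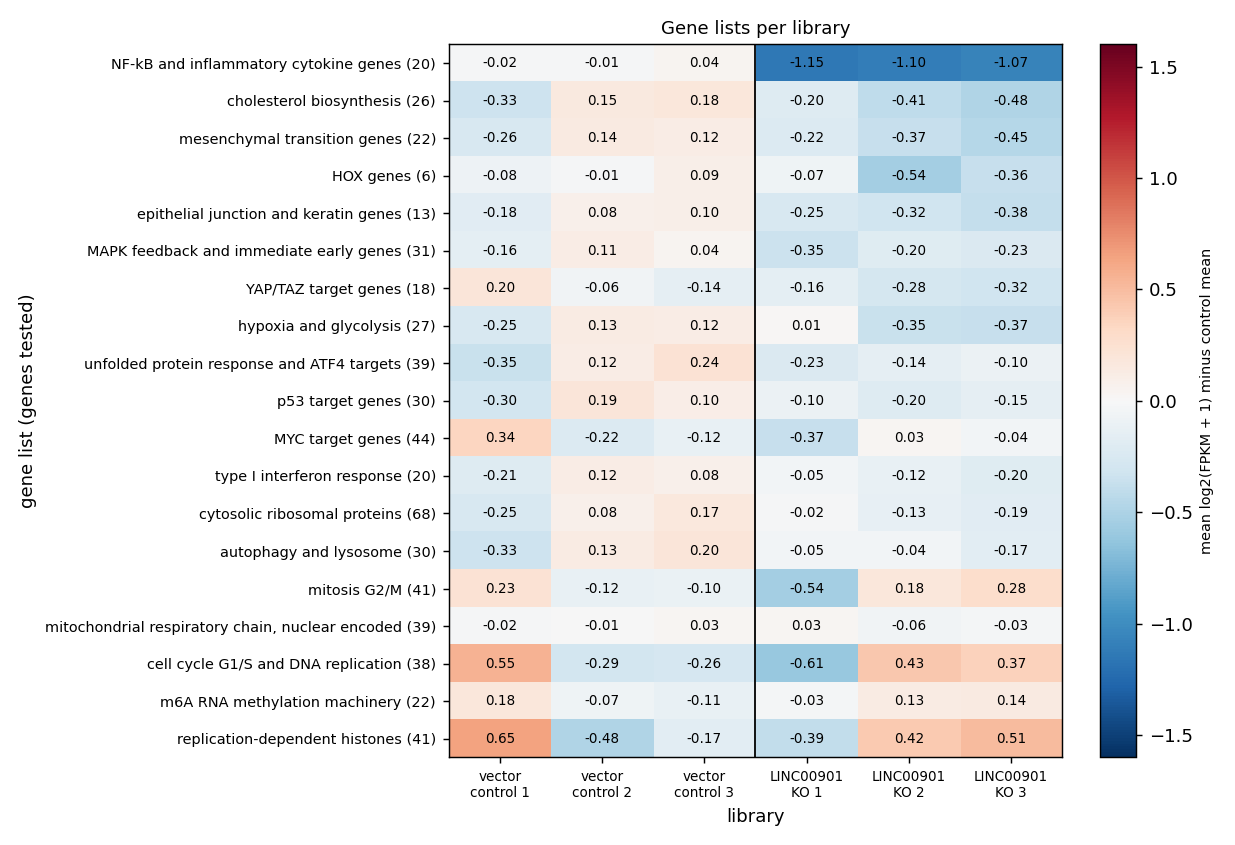
Mean log2(FPKM + 1) of each tested gene list in each library (columns), as the difference from the mean of the 3 vector controls, with the number of genes tested in parentheses (red, above the control mean; blue, below). The NF-kB list lies between -1.15 and -1.07 in the KO libraries, and the G1/S and histone lists are above the control mean in vector control 1, KO 2 and KO 3 and below it in the other 3 libraries.

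The remaining tested lists did not pass. The 38 G1/S and DNA replication genes had a median of 0.09 and a mean of 0.06, while camera placed the list lower (adjusted p = 0.436). The 41 mitosis genes had a median of -0.02 (adjusted p = 0.129). In both lists 0 members were called over all genes and 0 adjusted over the list alone. Both lists divided the libraries within each group, and G1/S genes lay 0.55 above the control mean in vector control 1 and -0.61 from it in KO 1. Of 41 tested replication-dependent histones, HIST1H2AC and HIST1H3F rose and 0 fell, and 3 were higher adjusted over the list alone. The list had a median of 0.14 (adjusted p = 0.648). In the p53 list GADD45A was the single call of 30 members, and 3 were lower adjusted over the list alone (median -0.01, adjusted p = 0.216). In the interferon list IFIT3 (-1.38) and OASL (-1.10) fell, and 6 members were lower and 4 higher adjusted over the list alone. The median of 0.07 and the mean of -0.12 differed in sign (20 members, camera lower, adjusted p = 0.257). Of 13 epithelial genes 0 were called, with 2 lower and 1 higher adjusted over the list alone (median -0.04, adjusted p = 0.158). Of 39 unfolded protein response genes 0 were called, with 4 lower and 6 higher adjusted over the list alone (median -0.15, adjusted p = 0.158). Of 39 nuclear genes of the respiratory chain 0 were called on either adjustment (median -0.00440, adjusted p = 0.154). HOXB9 (-1.53) was the single call among 6 HOX genes (median -0.19, adjusted p = 0.158). The protease gene CTSL (-0.82) was the single call among 30 autophagy and lysosome genes (median -0.11, adjusted p = 0.0717). Each was also the single gene lower adjusted over its list alone.

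Markers of other cell types were mostly below the filter. Of 24 neuroendocrine genes 4 were tested, and SCG2 and MAP2 (-1.08) fell. Of 22 leukocyte genes 3 were tested. LYZ, the lysozyme gene, was listed at 0 in every vector control and rose to 1.49 ± 0.317 FPKM (n = 3) in the KO libraries. The class II gene HLA-DRA fell from 2.96 ± 1.45 FPKM (n = 3) and was listed at 0 in every KO library. Of 27 acinar and ductal genes 2 were tested and 0 called. The mitochondrially encoded genes gave 0 tested members because their rows were at 0.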

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

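The term for the division of the libraries, the GC and length correction, the joined rows and the term together with an estimated correlation were tested after the result was seen, and the rest was fixed before. The count of 130 called genes rose to 241 without a filter (117 of the 130 among them), to 240 with the term for the division of the libraries (129 of the 130) and to 4020 with robust limma and array weights (all 130), which gave vector control 1 a weight of 0.151 and KO 1 one of 0.333. It fell to 59 with a filter at 5 FPKM, where fewer genes were tested, and to 31 at an adjusted p below 0.01. Leaving out 1 library gave 25 (without KO 3) to 1329 (without vector control 1). The other alternatives gave 99 to 143. With the replicate number as a block, 7 genes were called, all 7 of them lower and among the 130. The main differences within the groups did not follow the replicate numbers. This cannot exclude a shared day or batch, which the labels do not state. Same-numbered libraries deviated from their group means with correlations of -0.374, -0.153 and -0.264, and 0 correlated best with its own number. Of the calls added to the 130, 41.4% without vector control 1 and 44.2% with array weights had a limma p below 0.05 for the division of the libraries. Among all tested genes that share was 30.8%. Without vector control 1 the remaining controls lie on the same side of the division, so part of the added calls may follow it. The cause of the higher counts was not tested further.

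Of the 8 lists past camera, 4 passed with a filter at 5 FPKM, 4 with quantile normalization, 6 with the GC and length correction, 1 with an estimated correlation and 1 with fry. The correction ended the mesenchymal (0.0564) and YAP/TAZ (0.0706) calls. Over all 19 lists, 7 to 11 passed with 1 library left out (7 without vector control 2 or 3 or KO 3, 11 without KO 2). The NF-kB list passed in every setting that changed a single choice, with adjusted p up to 0.0141. With the term for the division and an estimated correlation together its adjusted p was 0.0576, and 0 lists passed. The G1/S list turned higher with robust limma and array weights (adjusted p = 0.00414) and without KO 1 (0.0346), and its adjusted p ranged from 0.0320 to 0.371 with 1 library left out. Both turns go with the division of the libraries. The G1/S mean was -0.61 in KO 1, which was left out or had a weight of 0.333, against 0.43 and 0.37 in KO 2 and 3. It was 0.55 in vector control 1, with a weight of 0.151, against -0.29 and -0.26 in vector control 2 and 3. With the term for the division of the libraries the histone list turned lower (adjusted p = 0.00136), and G1/S (1.82e-06) and mitosis (2.80e-05) passed as lower. The ribosomal (0.0692) and hypoxia (0.0870) calls were lost with it. Of the other lists not past camera, 4 passed without vector control 1, 2 without KO 1, 2 without KO 2 and 1 without KO 3. With robust limma and array weights 3 passed, and without a filter 3. G1/S also passed, as lower, without KO 2. The replicate block ended no list call. The cause was not tested in the other cases.

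Of the 27 called genes the text names by rule, none changed sign in the settings run. RGS4, STC1, SCG2, PDLIM1, AKR1B1, SLC6A12 and MMP3;MMP10 stayed called in each. Calls were lost for 16 named genes without KO 2 and 16 without KO 3, 11 without vector control 2, 10 without vector control 3, 7 without KO 1 and 20 with the block. The least stable were KLF4, lost in 9 of 16 settings (adjusted p up to 0.241), GADD45A in 8 of 17 (0.224) and NDRG1 in 7 of 16 (0.184). The alternatives for LINC00901 and for the authors' own p-values were not run, since the table used has neither. Unknown depth limits low genes most.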

Other observations

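The tests of other splits, swapped labels, S phase, copy number and leukocytes in this part were chosen after the result was seen. The 6 libraries divided along a line that crossed the groups, with vector control 1, KO 2 and KO 3 on one side and KO 1, vector control 2 and vector control 3 on the other. PCNA, the replication clamp, stood at 187.91, 165.77 and 158.72 FPKM in the former, against 44.99, 56.70 and 56.88, and TFRC, the transferrin receptor, at 126.53, 93.92 and 96.48 against 29.02, 22.17 and 21.26. The thioredoxin-binding TXNIP went the other way, at 24.22, 27.84 and 31.31 FPKM against 191.75, 289.52 and 291.61. So did the cyclin-dependent kinase inhibitor gene CDKN1C, at 0.99, 0.63 and 0.82 against 4.33, 10.08 and 11.14, and the clock gene NR1D1, at 3.19, 6.99 and 6.09 against 19.86, 52.28 and 50.90. These genes were chosen after their values were seen.

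Some of the lists fixed beforehand followed the same line, while others, such as the p53 (median log2 difference 0.02), interferon (0.05), MAPK (0.08) and YAP/TAZ (0.08) lists, had at least 562 of 10000 random lists as high. Between the 2 sets, G1/S and DNA replication genes were lower in KO 1 and vector control 2 and 3 in 36 of 38 members (median log2 difference -0.84), histones in 40 of 41 (-0.86) and mitosis genes in 36 of 41 (-0.46), where the lowest medians of 10000 random lists of the same size and expression were -0.37, -0.32 and -0.35. Ribosomal protein genes were lower there in 3 of 68 members (median 0.27, highest random list 0.23) and cholesterol genes in 8 of 26 (0.42, highest random list 0.30). The NF-kB list differed too (0.41, with 1 of 10000 random lists as high). The sets are uneven over the groups, so these differences carry part of the KO effect, and with a term for each the NF-kB median between the sets was 0.11. The sets were read from the values and are not groups of the study, so these figures describe the 6 libraries and are not tests between conditions.

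Several explanations bear on this division. After each library's trend with GC content and transcript length was removed, 79.1% of the genes called between the sets stayed called and their median absolute log2 difference went from 0.81 to 0.74, which argues against that bias as the whole cause. If the labels of KO 1 and vector control 1 were swapped, the groups as given would be a mix, and the 8 other mixing divisions called 0 genes. They called 130, which argues against a swap as the whole cause. The correlations do not decide, since KO 1 lay nearer to KO 3 (r = 0.935) than to vector control 3 (0.921), while vector control 1 also lay nearer to KO 3 (0.932) than to vector control 3 (0.906). A swap beside a further difference between the cultures stays open, since the exchanged labels call 384 genes and LINC00901 has no value. A different share of cells in S phase predicts that replication and histone genes move together, and the median of -0.84 for replication genes, with -0.86 for histones, is consistent with it as a hypothesis. What could have set that share, such as density, time since feeding or day of harvest, stays open because the labels give none of these, and no biological explanation from the design was tested.

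Of the 10 ways to divide the 6 libraries into 3 and 3, 2 called as many genes as the real groups. These were the real one with 130 and the division described above with 384, while the other 8 called 0. With 10 divisions no share under 0.05 can be reached, and the count of 384 points to a structure of the samples. For the NF-kB list, uneven spread of the 2 sets over the groups was weighed as an explanation. The median log2 fold change of the list was -0.97 for KO 1 against vector control 2 and 3 and -0.90 for KO 2 and 3 against vector control 1, so the sets do not account for it. A lower NF-kB output in the KO cells is therefore a hypothesis that may concern the knockout or the cells it was made in, since the labels do not say whether the libraries came from a single clone.

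For the genes lower in the KO libraries, loss of a genomic segment and leukocytes in the control cultures were weighed. Joined rows such as MMP3;MMP10 (-7.75) were not placed in the gene order, so the test of neighbours leaves them out. The 151 nearest tested neighbours of 76 lower genes had a median log2 fold change of -0.0300, far from the fold changes of the lower genes. This argues against segments of several expressed genes as the source of most of them, but a median cannot show segments behind a few. In the other direction, 11 of 10000 random gene lists had neighbours as low. Of the 151 neighbours, 10 were themselves called lower, against 81 of all 9624 tested genes. The 5 adjacent pairs of lower genes equalled the highest count in 1000 permuted gene orders. This count also leaves out the joined rows, so no pair with MMP3;MMP10 could enter it. Leukocytes that supplied these genes, whose median vector control mean was 9.13 FPKM, would bring LAPTM5, which reached 0.09 FPKM at most in the vector controls. A test on PTPRC, fixed before the result was seen, was set aside because PTPRC was listed at 0 in all 6 libraries and an exact 0 can be unmeasured. A few leukocytes as the source of the class II genes HLA-DRA (-1.91) and HLA-DRB1 (-2.58), which fell, cannot be told apart from a change in the cells themselves. CD74 was below the filter and not tested, at 0.57, 1.15 and 1.28 FPKM in the vector controls and 0.13, 0.49 and 0.53 in the KO libraries. Of LAPTM5, CORO1A, LCP1 and CD52, 0 were higher in every vector control, but only CORO1A was above the filter. Loss of segments behind some of the lower genes stays open, as do deletion or silencing of single genes and selection of a clone.

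As a hypothesis, KO and control cells could differ in copy number over longer segments, since fold changes of adjacent genes correlated at r = 0.108 (at most 0.0407 in 10000 permuted gene orders). Of 4 widths tried for windows of adjacent tested genes, the 2 widest gave windows beyond 1000 permuted orders. With 61 genes these were 147 overlapping windows on chromosomes 11, 14 and 20, all lower in the KO libraries. Of the 147, 47 on chromosomes 14 and 20 had the same sign in both partial comparisons. Those set KO 1 against vector control 2 and 3, and KO 2 and 3 against vector control 1. However, 8 of the 9 other divisions of the libraries also gave windows beyond the permuted orders at this width, up to 333. With 15 genes the bound of 0.78 exceeded a change from 2 to 3 copies (0.58), and 0.2% of simulated segments with such a change were found, so that width cannot decide. The lowest window of 15 genes, at -0.51, held the NF-kB list member NFKBIA (-1.46) and lay within the bound. With 31 genes the bound was 0.41, 87.2% of simulated segments with such a change were found and 0 real windows lay beyond it, and with 61 genes all were found while the lowest real window was at -0.33. These values go against a change of that size over long segments in all cells, and a smaller change or one in part of the cells stays open.

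Some single genes stood out. MTAP, CDKN2A and CDKN2B, adjacent on chromosome 9 and known to be deleted in this line, reached at most 0.02 FPKM in all 6 libraries. RELN stood at 1.16, 1.27 and 1.31 FPKM in the vector controls, RYR2 at 0.71, 0.72 and 0.70 and ZNF385D at 0.91, 0.67 and 0.83, and all 3 were listed at 0 in every KO library. These 3 were chosen after their values were seen.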
